A study of Mus musculus with 12 samples.

How the data were processed

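The deposited values are counts, whole numbers for 39086 Ensembl genes with 1 column per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, HTSeq 0.5.4p3 and the build mm10. The annotation release, the strand setting and the counting mode are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. Symbols and positions came from GENCODE vM21 for 37607 identifiers (96.2%). The cDNA was made with the Ovation RNA-Seq V2 kit.

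Genes were kept by edgeR's filterByExpr (17087 of 39086), libraries were scaled with TMM factors, and 4 group means were fitted over the 12 libraries with 8 residual degrees of freedom. Comparisons used edgeR's quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over the 17087 genes with calls at an adjusted p below 0.05. The common biological coefficient of variation was 0.536. Fold changes are log2 with the standard error from the fit, and CPM are given as mean and SD over the 3 libraries of a group. A set of 33 gene lists was tested with limma's camera at a preset correlation of 0.01, adjusted over 99 tests for the 3 diet comparisons and over 99 for the 3 EEC against non-EEC comparisons, and again with an estimated correlation and with fry. With an estimated correlation 0 lists were called in any comparison, and in no list called by camera did median, mean and direction differ in sign. The variant with an estimated correlation also missed secretory granule genes in EEC against non-EEC, where 30 of 30 were higher. A missing call by that variant therefore does not decide whether a list moved. The groups, comparisons, tests and gene lists and most alternatives were set before the data were examined.

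Named genes followed a rule. For each comparison it took up to 10 genes higher and 10 lower with the largest change among those called, with a mean of at least 10 CPM in the higher group and no overlap between the libraries compared (10% of genes by chance for 3 against 3), without unnamed genes. For the difference of diet effects the rule set no overlap condition and asked for 10 CPM in the highest group mean. It also took up to 4 called members of each list with the smallest adjusted p (or 2 members if none was called), and Neurog3, Chga and the hormones. Genes with 3 or fewer counts over the libraries of 1 group were left out, a choice made after values were seen, and Maoa and Lpar5 in EEC against non-EEC were named after their values were seen.

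The alternatives were RLE and upper quartile factors, no filter on low counts, a filter of 5 CPM in 3 libraries, robust estimation, DESeq2, limma-voom with quality weights, only the 6 libraries compared, a replicate block and leaving out each library in turn. Added after the data were seen were a T cell score as a covariate, tests of genes restricted to EEC, and runs with 1 library of an ND group. As a self-test, counts were simulated for the tested genes from the fitted means, library sizes and trended dispersions, with no diet effect except in 200 genes of at least 10 CPM given a known change. In each diet comparison edgeR then called 4 of 67 genes changed 2-fold (6.0%), 36 of 67 changed 4-fold (53.7%) and 66 of 66 changed 16-fold, and 4 (EEC) and 1 (non-EEC) of 16887 unchanged genes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.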

Results

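The libraries came from jejunal villi of male C57BL/6N mice with 1 Neurog3 allele that carries an eYFP reporter. Neurog3 encodes the transcription factor that starts endocrine differentiation in the gut, so the reporter marks enteroendocrine cells (EEC), the hormone cells of the epithelium. The mice were 12 weeks old and had eaten a normal diet (ND) or, from 8 weeks of age and for 4 weeks, a high fat diet (HFD). Enriched villi were dissociated and sorted by fluorescence into eYFP-positive cells (EEC) and eYFP-negative cells (non-EEC). Each of the 4 groups held 3 libraries, 12 in all. Total counts in replicates 1, 2 and 3 were 11570892, 9543183 and 29054281 in ND EEC, and 16331053, 11083904 and 12721405 in HFD EEC. In ND non-EEC they were 12830582, 11638584 and 15426107, and in HFD non-EEC 17685977, 10775776 and 10463504. Principal components were computed from log2 CPM (counts scaled to library size) of the genes with the highest variance only. The first component held 65.7% of the variance of these genes and parted the populations. EEC libraries lay between -96.0 and -27.8 and non-EEC libraries between 25.4 and 113.2. The second held 21.9% and parted the diets, with ND libraries at or below -7.7 and HFD libraries at or above -5.3. The labels name 3 mice per diet and do not say which EEC and non-EEC libraries share a mouse. The main fit treated the 12 libraries as independent, so p-values measure the spread between libraries and ignore any pairing by mouse. This bears on EEC against non-EEC and on the difference of diet effects. With a replicate block the genes lower in EEC under HFD went from 645 to 1042. Genes with a positive or negative difference of diet effects went from 77 and 8 to 64 and 20. Positions are on mm10 from the GENCODE vM21 annotation.

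The comparison of EEC with non-EEC over both diets asked which transcripts mark the sorted hormone cells. Neurog3 (chromosome 10, 62133090 to 62134763) had 178 ± 106 CPM (SD, n = 3) in ND EEC and 76.8 ± 61.4 in HFD EEC, against 0.472 ± 0.343 in ND non-EEC and 0.848 ± 0.529 in HFD non-EEC. Its log2 fold change was 7.46 ± 0.63 (SE; adjusted p = 8.23e-06). Chga (chromosome 12, 102554969 to 102565028), which encodes the granule protein chromogranin A, had 1953 ± 765 CPM in ND EEC and 4441 ± 1386 in HFD EEC, against 66.8 ± 91.4 and 35.1 ± 4.996 in the non-EEC. Hormone genes were higher in EEC for 17 of 18 list members, with a median of 4.75. Tac1 (tachykinins) was highest at 7.32 ± 0.54, followed by Cartpt at 6.04 ± 0.78, Gcg (proglucagon, the precursor of GLP-1) at 5.92 ± 0.88 and Ghrl (ghrelin) at 5.63 ± 0.79. Sst, Sct, Cck, Gip, Pyy and Nts followed at 4.93, 4.78, 4.57, 4.03, 3.95 and 3.46. Endocrine transcription factors were higher for 24 of 25 genes, among them Insm1 (6.83 ± 0.41), Pax4 (6.74 ± 0.57) and the serotonin cell factor Fev (6.66 ± 0.70). The kinase gene Pak3 was higher by 7.32 ± 0.45. Secretory granule and exocytosis genes were higher for 30 of 30, including Rab3c (6.28) and Pam (4.13), the enzyme that amidates peptide hormones. Tph1, the rate-limiting enzyme of serotonin synthesis, rose by 5.65 ± 0.71 within an enterochromaffin list in which 14 of 15 genes were higher and 1, Maoa, was lower (-1.54 ± 0.41).

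Genes that let EEC sense nutrients and fire were also enriched. Among nutrient and hormone receptors 19 of 25 were higher, with Galr1 at 6.40, the irritant channel Trpa1 at 6.21 and the short-chain fatty acid receptor Ffar2 at 5.03. The lysophosphatidic acid receptor Lpar5 was lower (-1.22 ± 0.40, adjusted p = 0.0458). This call held without ND EEC replicate 1 or HFD EEC replicate 2, and without ND non-EEC replicate 3 or HFD non-EEC replicate 1. The other runs without 1 library gave an adjusted p of 0.0692 to 0.113, and over all alternatives it ran from 0.0055 to 0.212. Channels and related genes of excitable endocrine cells were higher for 18 of 18, including the sodium channel Scn3a (6.34 ± 0.50). Camera gave these 6 endocrine lists adjusted p between 8.37e-24 and 3.00e-12, and adjusted p = 0.179 to 0.291 with an estimated correlation. Adjusted over the list alone, 17 of 18 hormone genes, 25 of 25 transcription factors and 30 of 30 granule genes were higher. Outside the endocrine lists, the small heat shock gene Hspb1 (4.18 ± 0.49), the intermediate filament gene Vim (3.36 ± 0.42), the lipoprotein receptor Scarb1 (3.12 ± 0.34), Cd44 (1.71) and the clock genes Cry2 (1.78) and Per2 (1.26) were higher in EEC. The test called 3685 of 17087 genes, 2353 higher and 1332 lower in EEC, and camera called 20 of 33 lists (6 up and 14 down). Leaving out 1 library gave 2787 to 3810 genes, of which 771 (without HFD EEC replicate 1) to 1449 (without HFD EEC replicate 2) were lower.

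Lymphocyte transcripts were the clearest group on the non-EEC side. Thy1 (-3.53 ± 0.47), Cd3d (-2.89 ± 0.54) and Lck (-2.79 ± 0.53), all markers of T cells, were among 17 of 18 T cell genes lower in EEC (list median -2.74, camera adjusted p = 1.44e-08, and 0.494 with an estimated correlation), and 17 were lower adjusted over the list alone. The B cell list had a median of -2.39 with 3 of 10 genes lower (camera adjusted p = 0.00105, and 0.494 with an estimated correlation). Goblet cell genes had a median of -1.49 with 7 of 12 lower, among them Zg16, a mucus lectin gene (-2.45 ± 0.64), and tuft cell genes a median of -1.55 with 4 of 13 lower, among them the phospholipase gene Plcg2 (-1.55 ± 0.29). Their adjusted p were 0.0182 and 0.00152 by camera, and 0.638 and 0.494 with an estimated correlation. Single genes lower in EEC included Rest, the repressor of neuronal genes (-2.22 ± 0.40), the immunoproteasome gene Psmb9 (-1.71 ± 0.26), the lipogenic regulator Srebf1 (-1.33 ± 0.25) and the proliferation gene Pcna (-1.10 ± 0.23). Cell cycle, interferon response, fatty acid oxidation and oxidative phosphorylation genes were also lower as lists (medians -1.06, -0.86, -0.64 and -0.64, camera adjusted p from 2.70e-06 to 0.00109), and with an estimated correlation their adjusted p were 0.494 to 0.553. Enterocyte markers (median -0.89, camera adjusted p = 0.128) and stem cell markers (median -0.21, adjusted p = 0.773) were not called.

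**Figure D1:**
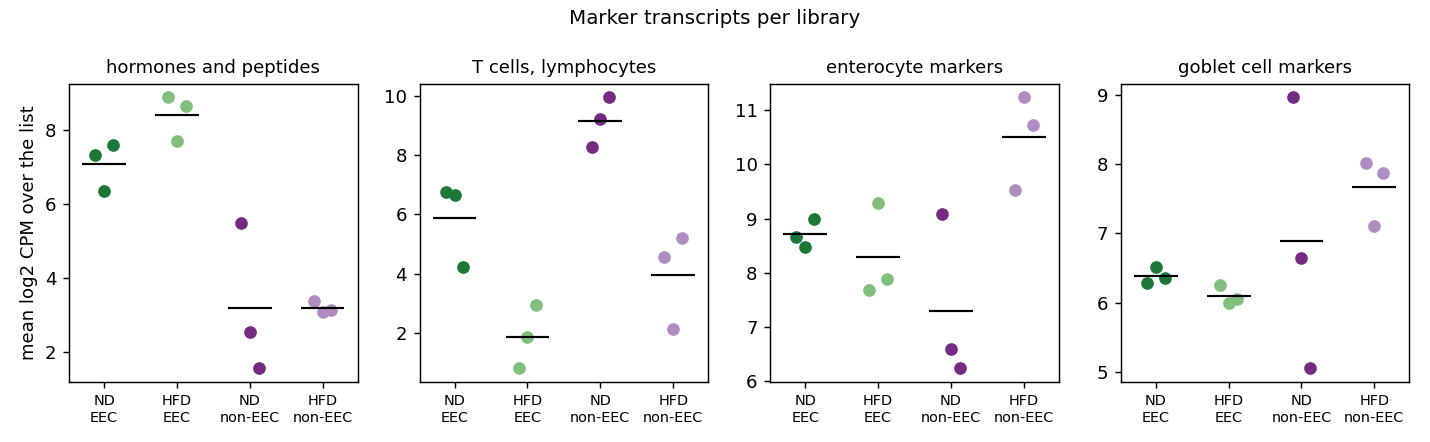
Mean log2 CPM over the genes of 4 lists (hormones, T cells, enterocyte and goblet markers), with 1 point per library (n = 3 per group) and a line at each group mean. Hormone scores lay between 6.35 and 8.89 in the EEC and between 1.57 and 5.48 in the non-EEC, where ND non-EEC replicate 1 had the 5.48.

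The same comparison within each diet asked whether the endocrine profile held under ND and under HFD. Under ND, Neurog3 (8.50 ± 0.93), Tac1 (7.62 ± 0.77), Insm1 (7.06 ± 0.58) and Chga (4.87 ± 0.95) were higher in EEC. Pyy, which encodes the satiety peptide YY, differed by 2.26 ± 0.89 (adjusted p = 0.112) and Cck by 2.62 ± 1.45 (adjusted p = 0.261), and neither was called. Without ND non-EEC replicate 1, which carried hormone transcripts, these became 4.75 for Pyy (adjusted p = 5.45e-04) and 7.40 for Cck (adjusted p = 0.00271), and over all alternatives the adjusted p ran from 1.95e-04 to 0.703 for Pyy and from 7.25e-04 to 0.738 for Cck. Hormone genes had a list median of 3.29 (camera adjusted p = 2.19e-09, and 0.364 with an estimated correlation), with 8 of 18 higher over all genes and 15 adjusted over the list alone. The fatty acid activating enzyme Acsl3 (2.27 ± 0.40), the glutathione synthesis gene Gclm (1.79 ± 0.32) and the sulfotransferase gene Sult1d1 (1.93 ± 0.39) were higher in ND EEC, while Thy1 (-3.51 ± 0.63) and Psmb9 (-2.03 ± 0.37) were lower. T cell genes had a median of -3.01, with 8 of 18 lower over all genes and 18 adjusted over the list alone (camera adjusted p = 2.33e-08, and 0.494 with an estimated correlation). Enterocyte markers pointed up in ND EEC with a median of 0.75 and 0 of 27 called (camera adjusted p = 2.27e-04, and 0.639 with an estimated correlation). The test called 2189 genes, 1351 higher and 838 lower, and this number was 1193 without ND EEC replicate 3 (934 higher and 259 lower), 936 without ND non-EEC replicate 2 (655 and 281) and 974 without ND non-EEC replicate 3 (734 and 240).

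Under HFD endocrine genes were again higher in EEC, and absorptive genes were lower. Cartpt was higher by 8.92 ± 1.26, Tac1 by 7.02 ± 0.75, Chga by 6.98 ± 1.05, Insm1 by 6.60 ± 0.57, Neurog3 by 6.42 ± 0.86 and Pyy by 5.64 ± 1.04. Hspb1 (6.25 ± 0.77) and Vim (5.38 ± 0.66) were higher as well. The water and glycerol channel Aqp3 (-3.46 ± 0.74), the glutathione transferase Gsta1 (-3.13 ± 0.66), the retinoid enzyme Aldh1a1 (-2.70 ± 0.54), catalase, Cat (-2.15 ± 0.42), and the fatty acid oxidation enzyme Acadm (-1.60 ± 0.34) were lower in EEC, as was Thy1 (-3.54 ± 0.72). Enterocyte markers had a median of -2.35 with 8 of 27 lower over all genes and 22 adjusted over the list alone (camera adjusted p = 4.78e-10, and 0.494 with an estimated correlation). Fatty acid oxidation genes had a median of -1.33 with 15 of 29 lower and 24 adjusted over the list alone (camera adjusted p = 3.77e-11, and 0.346 with an estimated correlation). T cell genes had a median of -2.50, with 3 of 18 lower over all genes and 15 adjusted over the list alone (camera adjusted p = 1.75e-05, and 0.553 with an estimated correlation). The test called 2393 genes, 1748 higher and 645 lower, and this number was 1226 without HFD EEC replicate 1 (1172 higher and 54 lower), 1305 without HFD EEC replicate 3 (1225 and 80), 1428 without HFD non-EEC replicate 2 (1188 and 240) and 1298 without HFD non-EEC replicate 3 (1132 and 166). DESeq2 called 2254 higher and 1499 lower.

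HFD vs ND in EEC asked how the fat diet altered the hormone cells themselves. Pyy (chromosome 11, 102106676 to 102107832) averaged 120 ± 58.6 CPM (SD, n = 3) in ND EEC and 793 ± 281 in HFD EEC, a log2 fold change of 2.73 ± 0.90 (SE; adjusted p = 0.311). Cartpt differed by 2.20 ± 0.84, Nts by 1.90 ± 1.12, Sct by 1.34 ± 0.96, Chga by 1.19 ± 0.82, Gip by 1.10 ± 0.95, Sst by 1.05 ± 1.31, Cck by 1.01 ± 1.38, Ghrl by 0.60 ± 0.92 and Gcg by 0.11 ± 1.01. Neurog3 pointed the other way (-1.21 ± 0.66, adjusted p = 0.628), as did Insm1 (-0.91 ± 0.44). Gcg and Sst changed sign in some runs that left out 1 library. With a T cell score as a covariate Gcg, Sst, Ghrl, Nts, Gip, Cck and Chga turned negative and Neurog3 positive. That score parted the diets in EEC, at -1 or above under ND and -2.29 or below under HFD. The fit with it thus leaves little of the diet effect to test. The activity-induced factor Egr3 (3.83 ± 0.95, adjusted p = 0.131) and the neuropeptide precursor Vgf (1.98 ± 0.75) pointed up. The hormone list moved up with a median of 1.08 and 17 of 18 members positive (camera adjusted p = 6.88e-04, and 0.613 with an estimated correlation), with 0 members called adjusted over the list alone. Granule genes moved up with a median of 0.55 (camera adjusted p = 0.0481, and 0.871 with an estimated correlation), and endocrine transcription factors were not called (median -0.22, adjusted p = 0.568). Without ND EEC replicate 2 the hormone list was not called (adjusted p = 0.0849), and the granule list was not called without ND EEC replicate 2 (0.482), ND EEC replicate 3 (0.122), HFD EEC replicate 1 (0.371), HFD EEC replicate 3 (0.138), HFD non-EEC replicate 1 (0.0513) or HFD non-EEC replicate 2 (0.0535). T cell genes had a median of -4.42 in the same comparison, and with a T cell score as a covariate the hormone list pointed down and was not called (adjusted p = 0.743). Over its alternatives the hormone list's adjusted p ran from 3.19e-06 to 0.743, and that of Pyy from 0.0421 (DESeq2) to 0.998.

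Of 33 lists camera called 14 for diet in EEC, while fry called 2, the T cell and interferon response lists. No single gene passed the threshold in the EEC. edgeR called 0 genes, with 1613 at an unadjusted p below 0.05 (717 higher and 896 lower), while DESeq2 called 465 (143 higher and 322 lower), limma-voom with quality weights 8 (7 higher and 1 lower), and edgeR without a filter on low counts 270. The number was 214 without ND EEC replicate 3 (11 higher and 203 lower) and 1 without HFD EEC replicate 3. Counts were simulated with the depth and trended dispersions of these libraries and no other diet effect. There edgeR recovered 6.0% of 2-fold, 53.7% of 4-fold and 100% of 16-fold changes in genes of at least 10 CPM. Most 2-fold changes were thus not detectable in that setting with 3 libraries per group. The simulation did not use each gene's own spread, and its recovery of large changes did not carry over to the T cell list. That list had a median of -4.42 in the real data, with 0 of 18 genes called.

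Genes of fatty acid metabolism and sterol synthesis pointed up in HFD EEC, and edgeR called none of them in the full data. The fatty acid hydroxylase Cyp4a10 had 1.12 ± 0.444 CPM (SD, n = 3) in ND EEC and 14.7 ± 10.5 in HFD EEC, a log2 fold change of 3.68 ± 0.70 (SE; adjusted p = 0.0691). Malic enzyme Me1 differed by 2.46 ± 0.48 (adjusted p = 0.0691), the desaturase Scd1 by 2.39 ± 0.84 and the acyl-CoA thioesterase Acot1 by 1.46 ± 0.48. Cholesterol synthesis genes moved up with a median of 0.56 and 22 of 25 members positive, including Fdft1 (1.36 ± 0.39) and Hmgcs1 (1.10 ± 0.33). Camera called that list in HFD vs ND in EEC (adjusted p = 9.26e-06, and 0.392 with an estimated correlation), with 0 genes called adjusted over the list alone, and kept the call in each run that left out 1 library. Fry did not call the cholesterol list (adjusted p = 0.0843). Targets of PPAR, the fatty acid sensing nuclear receptors, moved up with a median of 0.61 and 20 of 24 members positive (camera adjusted p = 0.00143, and 0.506 with an estimated correlation), with 2 called adjusted over the list alone. Fatty acid oxidation genes had a median of 0.37 (camera adjusted p = 0.00773, and 0.821 with an estimated correlation) and fatty acid synthesis genes 0.38 (0.00514, and 0.452 with an estimated correlation). Lipid absorption and chylomicron genes were not called (median 0.20, camera adjusted p = 0.792). The PPAR list lost its call without ND EEC replicate 2 (0.0529). The oxidation list lost it without ND EEC replicates 2 (0.336) or 3 (0.0649) or HFD EEC replicate 2 (0.181), and the synthesis list without ND EEC replicate 3 (0.0846) or HFD EEC replicate 1 (0.0688). Me1 passed without ND EEC replicate 3 (adjusted p = 0.0444). Over all alternatives the adjusted p ran from 7.43e-05 to 0.978 for Me1, from 1.30e-05 to 0.912 for Cyp4a10 and from 0.0439 to 0.953 for Hmgcs1. Enterocyte markers had a median of -0.09 here and were not called (adjusted p = 0.0580), with a call down without ND EEC replicate 2 (0.0186), HFD EEC replicate 2 (1.27e-04), ND non-EEC replicates 1 (0.0247) or 3 (0.0365) or HFD non-EEC replicate 1 (0.0430). HFD EEC replicate 2 had the highest enterocyte score in EEC (mean log2 CPM 9.29, against 7.68 and 7.88 in the other HFD libraries and 8.47 to 8.99 under ND) and also the highest PPAR (6.01) and oxidation (6.33) scores. The T cell list moved down in the same comparison with a median of -4.42. With a T cell score as a covariate the PPAR (adjusted p = 0.266), oxidation (0.147) and synthesis (0.0873) lists were not called. In that fit enterocyte markers (4.78e-09) and lipid absorption genes (7.21e-04) were called down. The score follows diet in EEC, so that fit leaves little of the diet effect to test.

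Stress-response genes pointed up in HFD EEC as a list. Hspb1 (chromosome 5, 135887919 to 135889563) had 11 ± 5.19 CPM (SD, n = 3) in ND EEC and 115.6 ± 86.6 in HFD EEC, against 2.53 ± 1.18 and 1.56 ± 1.04 in the non-EEC. Its log2 fold change in EEC was 3.39 ± 0.66 (SE; adjusted p = 0.0691), that of the stress factor Atf3 3.18 ± 0.66 (adjusted p = 0.0761) and that of Ddit3 1.14 ± 0.39. Immediate early and heat shock genes moved up with a median of 1.43 and 21 of 22 positive (camera adjusted p = 3.98e-12, and 0.392 with an estimated correlation), with 15 adjusted over the list alone. Fry did not call this list (adjusted p = 0.0505). Unfolded protein response genes had a median of 0.44 (camera adjusted p = 0.00753, and 0.493 with an estimated correlation), not called without ND EEC replicate 2 (0.356) or with a T cell score as a covariate (0.439), in libraries where the T cell list had a median of -4.42. That score itself follows diet in EEC. Cell cycle genes had a median of 0.57, with Mcm7 at 1.04 ± 0.41 (camera adjusted p = 0.0249, and 0.871 with an estimated correlation), and lost the call without ND EEC replicate 2 (0.184), ND EEC replicate 3 (0.0591) or HFD EEC replicate 2 (0.928, direction down). The cell cycle score of HFD EEC replicate 2 was 5.05, against 3.93 and 3.4 in the other HFD EEC libraries and 3.54 to 3.74 under ND. The clock-linked repressor Nfil3 (2.02 ± 0.51), the lipase Mgll (2.05 ± 0.82), the incretin receptor Glp1r (1.36 ± 0.56) and the cation channel Trpm2 (1.49 ± 0.45) pointed up, and the glucose transporter Slc2a2 (-2.17 ± 0.88) and Cyp2c55 (-3.03 ± 0.85) down. Hspb1 passed without ND EEC replicate 3 (adjusted p = 0.0449), and its adjusted p over all alternatives ran from 3.61e-05 to 0.570.

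Camera called the T cell, B cell, myeloid, MHC class II and interferon response lists down in HFD EEC. edgeR called 0 of their genes over all genes in the full data. Thy1 (chromosome 9, 44043384 to 44048579) had 12.4 ± 8.86 CPM (SD, n = 3) in ND EEC and 0.398 ± 0.0475 in HFD EEC, a log2 fold change of -4.92 ± 0.73 (SE; adjusted p = 0.0683), and the T cell receptor gene Trac differed by -5.29 ± 1.01 (adjusted p = 0.0691). The T cell list had a median of -4.42 with 0 of 18 members positive (camera adjusted p = 1.28e-24, and 0.392 with an estimated correlation), and 17 fell adjusted over the list alone. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, had 432 ± 209 CPM in ND EEC and 70.2 ± 30.4 in HFD EEC (-2.62 ± 0.71, adjusted p = 0.176), and H2-Ab1 differed by -2.08 ± 0.60. MHC class II genes moved down with a median of -1.72 (camera adjusted p = 9.59e-05, and 0.392 with an estimated correlation), 5 of 10 adjusted over the list alone. Interferon response genes moved down with a median of -0.93, with Gbp7 at -2.85 ± 0.55 (adjusted p = 0.0691) and Zbp1 at -2.79 ± 0.55 (camera adjusted p = 1.70e-10, and 0.392 with an estimated correlation), 5 of 28 adjusted over the list alone. Itgax, an integrin of dendritic cells, differed by -2.79 ± 0.74 within a myeloid list with a median of -0.42 (camera adjusted p = 0.00473, and 0.392 with an estimated correlation), not called without ND EEC replicate 1 (0.0675) or HFD EEC replicate 2 (0.293). B cell genes had a median of -2.84 (camera adjusted p = 3.03e-04, and 0.404 with an estimated correlation), not called without ND EEC replicate 1 (0.0530). With a T cell score as a covariate camera called the B cell list up (adjusted p = 0.0214) and did not call the myeloid list (0.403). The score follows diet in EEC, so that fit leaves little of the diet effect to test. Without ND EEC replicate 3, Thy1 (adjusted p = 0.00147), Trac (0.00610) and Gbp7 (0.0490) passed, and over all alternatives the adjusted p of Thy1 ran from 2.10e-08 to 0.937.

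**Figure D2:**
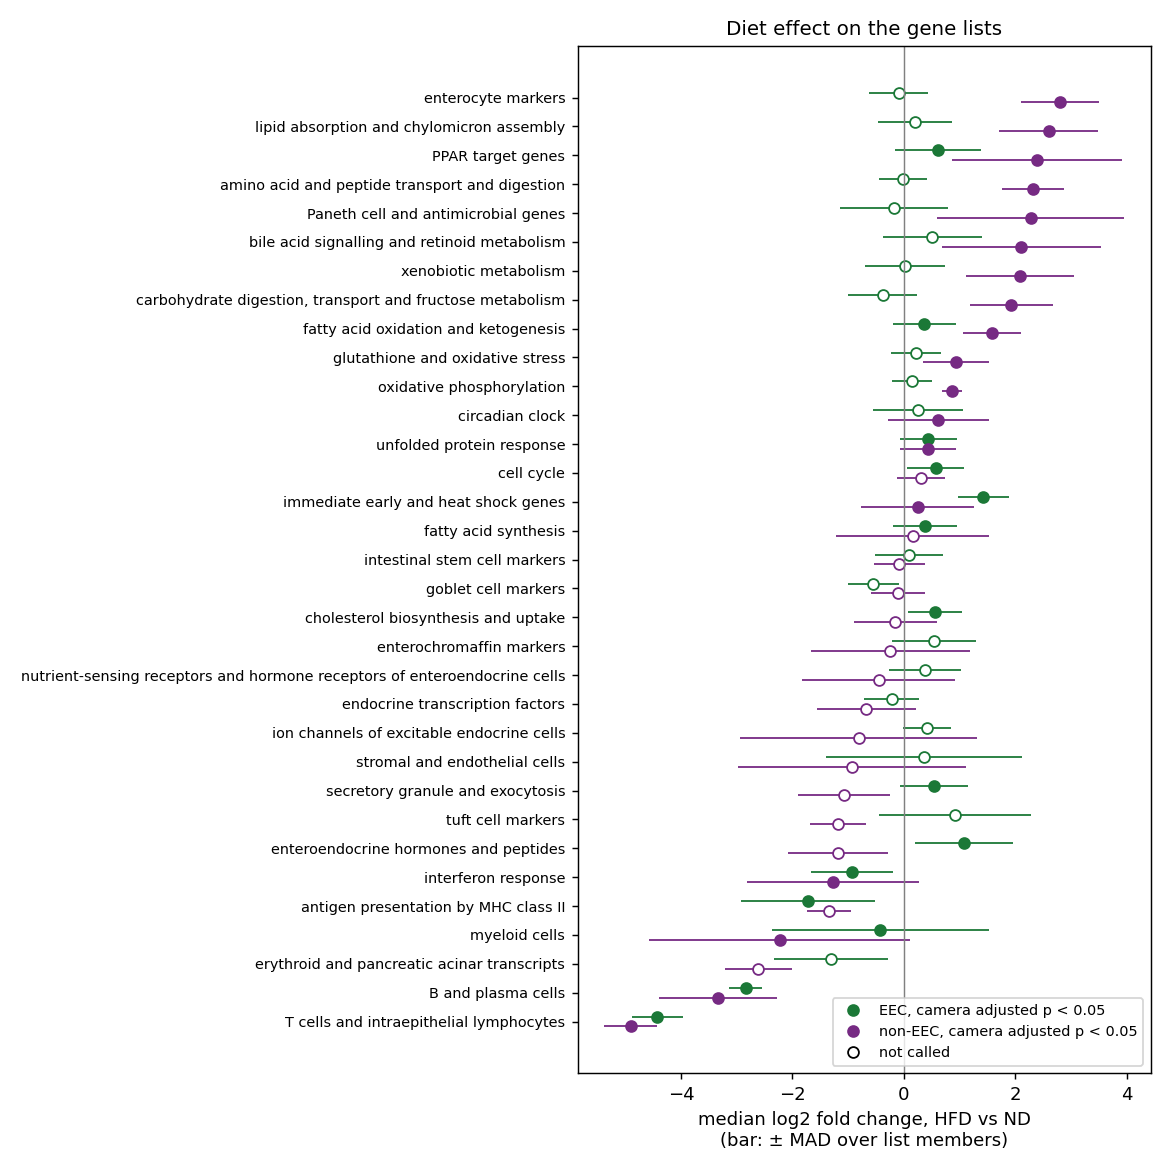
Median log2 fold change, HFD against ND, of the members of 33 gene lists in EEC (green) and non-EEC (purple). Bars give the median absolute deviation over list members, and filled points had a camera adjusted p below 0.05 (14 lists in EEC and 18 in non-EEC), such as the T cell list at -4.42 and -4.90.

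HFD against ND in the non-EEC asked what the diet did in the rest of the villus. Cyp4a10 (chromosome 4, 115518264 to 115533649) rose from 0.789 ± 0.806 CPM (SD, n = 3) to 109.2 ± 41.2, a log2 fold change of 7.14 ± 0.81 (SE; adjusted p = 0.00162). Other genes of fatty acid oxidation and its control rose as well, including the peroxisomal thiolase Acaa1b (4.46 ± 0.92), the pyruvate dehydrogenase kinase Pdk4 (4.33 ± 0.60) and Acot1 (4.32 ± 0.54). Me1, a member of the fatty acid synthesis list, rose by 4.36 ± 0.52. That list was not called and had a median of 0.16, with 2 of 17 genes higher and 3 lower. PPAR targets had a median of 2.39 with 20 of 24 higher, and fatty acid oxidation genes a median of 1.58 with 22 of 29 higher. Fabp1 (chromosome 6, 71199827 to 71205023), the liver-type fatty acid binding protein, rose from 794 ± 676 to 10890 ± 3981 CPM (3.78 ± 0.73), while Fabp2 rose by 3.49 ± 0.65, the fatty acid receptor Cd36 by 4.49 ± 0.78, Apoc2 by 4.68 ± 0.90, Acsl3 by 3.17 ± 0.42 and Slc27a2 by 3.00 ± 0.51. Lipid absorption and chylomicron genes had a median of 2.60 with 21 of 33 higher. Camera's adjusted p for the PPAR, fatty acid oxidation and lipid absorption lists were 1.14e-13, 3.02e-15 and 1.40e-15, and 0.392 for each with an estimated correlation, with 21, 27 and 27 genes higher adjusted over the list alone. The T cell list in the same libraries had a median of -4.90. Mitochondrial transcripts held 6.6, 11.6 and 10.9% of the counts in HFD non-EEC replicates 1, 2 and 3 against 6.5, 4.5 and 2.0% under ND. The TMM factors were 0.940, 0.732 and 0.840 against 1.003, 1.217 and 1.134.

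Other functions of absorptive cells rose alongside. Enterocyte markers had a median of 2.80 and ran from 1.66 to 3.96, with 17 of 27 higher over all genes and 27 adjusted over the list alone (camera adjusted p = 5.81e-15). ND non-EEC replicate 1 stood apart from its group, with an enterocyte score (mean log2 CPM) of 9.08 against 6.59 and 6.24, near the 9.52 of HFD non-EEC replicate 1. Its goblet score was 8.97 against 6.64 and 5.05. Amino acid and peptide genes had a median of 2.32 with 13 of 23 higher (5.78e-12), xenobiotic metabolism genes 2.08 with 12 of 30 higher (9.76e-12) and carbohydrate genes 1.93 with 8 of 20 higher (1.02e-08), including Pck1, the rate-limiting enzyme of gluconeogenesis (3.70 ± 0.76). Bile acid and retinoid genes had a median of 2.11 with 8 of 14 higher (2.15e-06), including Aldh1a1 (3.65 ± 0.56), glutathione genes 0.94 with 6 of 19 higher (3.92e-05), including Cat (2.08 ± 0.42) and Gclm (1.69 ± 0.32), and oxidative phosphorylation genes 0.87 (2.11e-08). With an estimated correlation the adjusted p of each of these 7 lists was 0.392. Adjusted over the list alone, 21 amino acid, 20 xenobiotic, 15 carbohydrate, 11 bile acid and retinoid, 7 glutathione and 13 oxidative phosphorylation genes were higher. Aqp3 (4.60 ± 0.79), the small GTPase Rab30 (4.70 ± 0.57), Sult1d1 (2.01 ± 0.39), the sterol carrier Stard4 (1.48 ± 0.33) and Atf3 (3.09 ± 0.66) rose too. Paneth and antimicrobial genes had a median of 2.28 with 1 of 17 higher (camera adjusted p = 0.00166, and 0.493 with an estimated correlation). Unfolded protein response genes had a median of 0.44 (0.00739, and 0.493 with an estimated correlation). Immediate early and heat shock genes had a median of 0.25 (0.0330, and 0.871 with an estimated correlation), not called without ND non-EEC replicates 1 (0.175) or 2 (0.186) or HFD non-EEC replicates 1 (0.0529) or 3 (0.203). Circadian clock genes had a median of 0.62 (0.0295, and 0.548 with an estimated correlation), not called without ND non-EEC replicates 1 (0.0654) or 2 (0.0564) or HFD non-EEC replicates 2 (0.0944) or 3 (0.0768). With a T cell score as a covariate, which follows diet in non-EEC, camera did not call the Paneth (adjusted p = 0.657), unfolded protein response (0.128) or clock (0.323) lists. Goblet markers (median -0.10, adjusted p = 0.124) and stem cell markers (median -0.08, adjusted p = 0.792) were not called, and goblet markers were called up without ND non-EEC replicate 1 (3.46e-04) or HFD non-EEC replicate 2 (0.0367).

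T cell genes fell in the non-EEC, with a list median of -4.90 against -4.42 in EEC. Thy1 fell from 140.6 ± 32.7 to 4.70 ± 2.11 CPM (SD, n = 3), a log2 fold change of -4.89 ± 0.67. The T cell genes Cd7 (-4.90 ± 0.85), Cd3d (-4.64 ± 0.81) and Lck (-4.45 ± 0.80), the dendritic cell integrin Itgax (-4.70 ± 0.80) and the B cell receptor component Cd79b (-4.32 ± 0.98) fell as well. The T cell list fell with a median of -4.90 and 17 of 18 genes lower, 18 adjusted over the list alone (camera adjusted p = 1.04e-12, and 0.392 with an estimated correlation). Interferon response genes had a median of -1.27, with Gbp2 at -4.79 ± 0.97 and Gbp7 at -3.83 ± 0.57, 7 of 28 lower and 12 adjusted over the list alone (camera adjusted p = 6.21e-05, and 0.392 with an estimated correlation). Myeloid genes had a median of -2.23 (0.0149, and 0.452 with an estimated correlation) and B cell genes -3.34 (6.35e-04, and 0.445 with an estimated correlation), with 4 of 14 and 4 of 10 lower adjusted over the list alone. Vim (-4.30 ± 0.63), Plcg2 (-2.41 ± 0.42), the desaturase Scd2 (-2.06 ± 0.40), the potassium channel Kcnh2 (-3.05 ± 0.51) and Glp1r (-4.01 ± 0.63) fell as well. MHC class II genes were not called (median -1.34, adjusted p = 0.0771), with a call down without ND non-EEC replicate 2 (0.0298) or HFD non-EEC replicates 2 (0.0121) or 3 (0.0259). The hormone list was not called (adjusted p = 0.783), and camera's direction for it was up although its median was -1.18. It was called up without ND non-EEC replicate 1 (0.0124), the library with a hormone score of 5.48. The test called 2549 genes, 985 higher and 1564 lower. That number was 4141 without ND non-EEC replicate 1 (2118 higher and 2023 lower), 1046 without ND non-EEC replicate 2 (185 and 861) and 1025 without ND non-EEC replicate 3 (230 and 795). It was 1026 without HFD non-EEC replicate 2 (263 and 763) and 1303 without HFD non-EEC replicate 3 (382 and 921). With a T cell score as a covariate it was 0, in a fit that leaves little of the diet effect to test because the score itself follows diet.

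**Figure D3:**
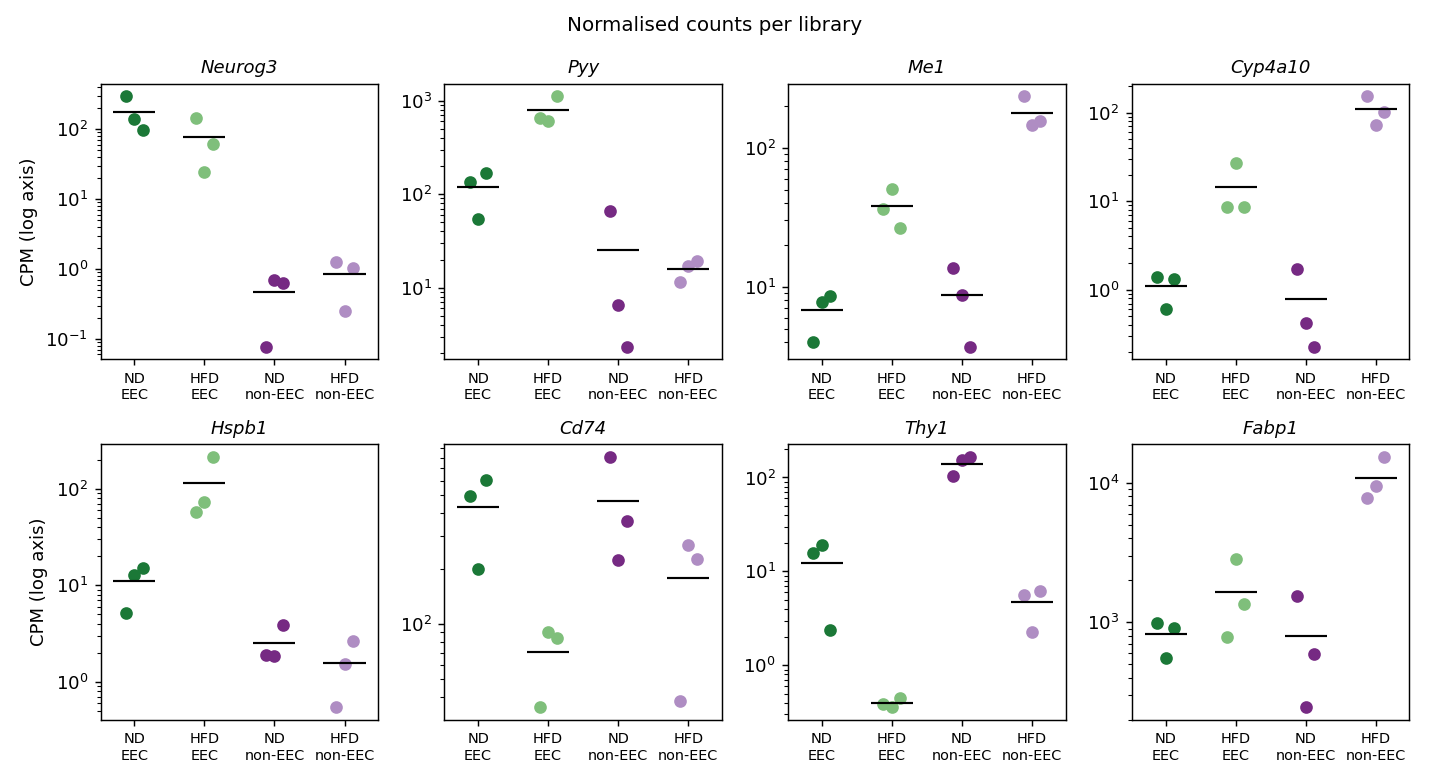
CPM on a log axis for 8 genes in each library (points, n = 3 per group), with a line at the arithmetic mean of each group. Fabp1 averaged 10890 CPM in HFD non-EEC and 794 in ND non-EEC, and Thy1 0.398 CPM in HFD EEC and 12.4 in ND EEC.

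The difference between the diet effects asked which genes responded differently in EEC and non-EEC. Ptgs2 (chromosome 1, 150100031 to 150108227), which encodes the inducible prostaglandin synthase, had 0.704 ± 0.547 CPM (SD, n = 3) in ND EEC and 39.7 ± 16.3 in HFD EEC, against 2.60 ± 1.798 in ND non-EEC and 0.4999 ± 0.652 in HFD non-EEC. Its interaction was 8.16 ± 1.29 (log2, SE; adjusted p = 0.0253). Glp1r (chromosome 17, 30901817 to 30940791) averaged 40.1 ± 10.7 and 102.8 ± 43.0 CPM in ND and HFD EEC, and 119.1 ± 28.1 and 7.24 ± 7.21 in ND and HFD non-EEC (interaction 5.37 ± 0.83). Egr3 (7.55 ± 1.39), Crmp1 (5.76 ± 0.87), B3galt5 (5.44 ± 0.81), Vim (4.04 ± 0.80) and Kcnh2 (3.71 ± 0.67) also had positive interactions. The detoxification genes Akr1c19 (-4.11 ± 0.68), Akr1c13 (-3.04 ± 0.53) and Sult1d1 (-3.08 ± 0.54), the haem exporter Flvcr1 (-3.35 ± 0.67), Dlg3 (-2.54 ± 0.47) and Pgap1 (-2.27 ± 0.43) had negative ones. Hspb1 (4.14 ± 0.92, adjusted p = 0.0699), Acsl3 (-2.73 ± 0.55, adjusted p = 0.0514), Fabp2 (-3.54 ± 0.86, adjusted p = 0.0841), Cartpt (5.75 ± 1.47, adjusted p = 0.0963), Acadm (-2.15 ± 0.47), Dpp4 (-2.94 ± 0.68) and Pyy (3.38 ± 1.24, adjusted p = 0.202) were not called, and without ND non-EEC replicate 1 Dpp4 (0.0102), Acadm (0.0136), Hspb1 (0.0206), Fabp2 (0.0216) and Acsl3 (0.0223) passed. The test called 85 genes, 77 with a positive and 8 with a negative interaction. With a replicate block it called 84 (64 and 20), against 1061 by DESeq2 (596 and 465) and 2183 by limma-voom (963 and 1220). Removing 1 library moved the count of 85 to 36, 6 and 1 without ND EEC replicates 1, 2 and 3. It moved to 0, 159 and 0 without HFD EEC replicates 1, 2 and 3. It moved to 1300 (458 positive and 842 negative), 0 and 15 without ND non-EEC replicates 1, 2 and 3, and to 41, 16 and 0 without HFD non-EEC replicates 1, 2 and 3. None of the named calls held in all of these runs.

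Among the lists called for the difference, enterocyte markers had the largest median and the smallest camera adjusted p. Enterocyte markers had an interaction median of -2.94 (camera adjusted p = 1.05e-18), carbohydrate genes -2.61 (4.73e-11), amino acid genes -2.39 (5.15e-14), lipid absorption genes -2.38 (4.74e-16), xenobiotic genes -2.31 (2.72e-14), bile acid and retinoid genes -2.22 (3.33e-05), PPAR targets -1.91 (4.94e-10), Paneth genes -1.80 (8.20e-04), fatty acid oxidation genes -1.27 (3.12e-11), oxidative phosphorylation genes -0.80 (2.22e-06) and glutathione genes -0.71 (6.96e-04). With an estimated correlation these adjusted p were between 0.392 and 0.462. Fry called 3 lists for the difference, fatty acid oxidation, PPAR target and xenobiotic genes. It did not call enterocyte markers (adjusted p = 0.0549) or lipid absorption, carbohydrate and amino acid genes (0.0641 each), nor the other lists called by camera. Over all genes edgeR in the full data called 0 of 27 enterocyte, 0 of 33 lipid, 0 of 24 PPAR, 1 of 30 xenobiotic and 0 of 29 fatty acid oxidation genes. Adjusted over the list alone 16, 18, 12, 12 and 11 had lower diet effects in EEC. Goblet genes had a median of -0.39 (0.0477, and 0.821 with an estimated correlation). Among runs without 1 library they kept that call only without HFD EEC replicate 1, ND non-EEC replicate 1 or HFD non-EEC replicate 2. The other such runs gave 0.0508 (without ND EEC replicate 3) to 0.378 (without ND non-EEC replicate 3). The T cell list was not called in the full data (median 0.55, adjusted p = 0.157), and was called up without ND EEC replicate 1 (0.0325), HFD EEC replicate 1 (0.0207) or HFD non-EEC replicate 3 (0.0117). The hormone list was not called (median 2.36, adjusted p = 0.122), with a call up without ND EEC replicate 3 (0.0405), HFD EEC replicate 2 (0.0405) or ND non-EEC replicates 2 (0.0349) or 3 (6.18e-04). Across the genes tested, the diet effects in the populations correlated at Pearson's r = 0.377 and Spearman's rho = 0.244, over genes that are not independent replicates. Of the genes that fell in non-EEC, 482 were lower in EEC at an unadjusted p below 0.05, against 82 from independence, and of those that rose 75 were higher in EEC, against 41.3. The labels name 3 mice per diet, so the populations are likely to share mice. Neither the correlation nor the overlap was set against a value that allows for this.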

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

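The tests of explanations and the counts over other splits of the samples in this part were chosen after the results were seen. The test of the difference between diet effects singled out 85 genes whose change from ND to HFD differed between EEC and non-EEC. The named ones were Ptgs2 (8.16), Egr3 (7.55), Crmp1 (5.76), B3galt5 (5.44), Glp1r (5.37), Vim (4.04) and Kcnh2 (3.71), and on the other side Akr1c19 (-4.11), Flvcr1 (-3.35), Sult1d1 (-3.08), Akr1c13 (-3.04), Dlg3 (-2.54) and Pgap1 (-2.27). Camera also singled out 12 lists, with medians of -2.94 (enterocyte), -2.61 (carbohydrate), -2.39 (amino acid), -2.38 (lipid absorption), -2.31 (xenobiotic), -2.22 (bile acid and retinoid), -1.91 (PPAR targets), -1.80 (Paneth), -1.27 (fatty acid oxidation), -0.80 (oxidative phosphorylation), -0.71 (glutathione) and -0.39 (goblet). Fry called only 3 of these, the xenobiotic, PPAR target and fatty acid oxidation lists. For the count of 85 genes, 7 of 100 splits of the libraries, the real one included, gave at least as many, with 1688 as the highest other. The 6 other splits kept the diet groups of the non-EEC libraries whole and so still held the diet effect of the non-EEC. They do not decide whether chance can be excluded for this count, and point to a structure of the samples. Glp1r, Vim and Kcnh2 fell in non-EEC, where the T cell list had a median of -4.90. For these genes a response to the diet cannot be told apart from a changed mix of sorted cells.

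T cell transcripts were lower under HFD in both sorted populations (list medians -4.42 in EEC and -4.90 in non-EEC), although the eYFP sort should remove lymphocytes from EEC. Library scaling, which would shift all lists alike, is argued against by the T list median lying -4.33 from the enterocyte median in EEC (median absolute deviations 0.46 and 0.53), and dilution by enterocytes in HFD non-EEC by the goblet median of -0.10 (median absolute deviation 0.48). Lymphocytes or their RNA among the sorted EEC of ND mice are a candidate source, since 18 of 18 T cell genes lay within 1 log2 unit of their median EEC to non-EEC ratio of -3.01 under ND, with Cd3e at 487, 359.9 and 55.1 CPM in ND EEC and 1606, 2244 and 2471 in ND non-EEC. Fewer lymphocytes in the villi of HFD mice cannot be told apart from a difference in preparation. The lowest ND score exceeded the highest HFD score in non-EEC by 3.09, and the labels do not say how the preparations were spread over the diets.

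Enterocyte genes were higher under HFD in non-EEC (median 2.80, median absolute deviation 0.70) and not in EEC (median -0.09). A lower share of lymphocytes as the whole cause would raise other epithelial markers too. Stem cell markers had a median of -0.08 (median absolute deviation 0.46) in the same libraries. Goblet markers were called up by camera without ND non-EEC replicate 1 (adjusted p = 3.46e-04) or HFD non-EEC replicate 2 (0.0367), so this cause is not decided. A larger share of enterocytes among the HFD non-EEC may have contributed, since the lowest of the 27 markers was 1.66. A lower share of lymphocytes could give that value as well. A response of enterocyte genes to the diet cannot be told apart from a larger share of enterocytes. The PPAR median minus the enterocyte median was -0.41 against summed deviations of 2.22.

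PPAR target genes pointed up in HFD EEC (median 0.61), with 0 of 24 called over all genes by edgeR in the full data, and the list was not called with an estimated correlation (adjusted p = 0.506), by fry (0.217) or without ND EEC replicate 2 (0.0529). More enterocytes carried into the EEC gate cannot be excluded. The enterocyte median was -0.09 (median absolute deviation 0.53), and it lay within the deviation of 0.77 of the PPAR genes from their median. HFD EEC replicate 2 had both the highest enterocyte and the highest PPAR score in EEC. A constant share of carried enterocytes that respond themselves cannot be told apart from a response of EEC, since the PPAR genes in EEC exceeded that prediction by a median of 0.99 with a median absolute deviation of 1.47. The response of EEC could be tested on 0 PPAR genes, as none was among the genes restricted to EEC (called higher in EEC under both diets with a fold above 4). Cidea came nearest, higher in EEC by 6.26 under ND (adjusted p = 0.0615) and 8.48 under HFD (0.0241), and its diet effect in EEC was not called (2.22 ± 1.24, adjusted p = 0.657).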

How the results depend on the processing

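The T cell score covariate, the tests of EEC-restricted genes, the runs with 1 library of an ND group and the counts over other splits were chosen after the results were seen. Of the counts under alternatives, 80 stayed within 1.5 times the reported number, 18 were larger and 29 smaller. Of the gene values, 2866 kept direction and call, 333 lost the call, 70 gained one and 13 reversed, and the 14 values of the correlation between diet effects stayed on their side (Pearson's r 0.229 to 0.421 without 1 library). DESeq2 called 3625 genes (EEC against non-EEC, ND), 3753 (HFD), 465 (diet in EEC), 4053 (diet in non-EEC) and 1061 (difference of diet effects). Limma-voom called 5140, 4385, 8, 6929 and 2183, and 5556 for EEC against non-EEC over both diets. Without a filter on low counts 270 genes were called for diet in EEC and 362 for the difference, and with only the 6 libraries compared 1120 for EEC against non-EEC under ND and 3211 under HFD (2082 higher and 1129 lower). Leaving out 1 library gave 936 to 3041 (EEC against non-EEC, ND), 1226 to 2680 (HFD), 0 to 214 (diet in EEC), 1025 to 4141 (diet in non-EEC) and 0 to 1300 (difference). With the T cell score as a covariate 977 genes were called over both diets, 187 under ND, 0 for diet in non-EEC and 42 for the difference. The score itself follows diet within each population, so this fit leaves little of the diet effect to test. With 1 ND non-EEC library 111 genes were called for diet in non-EEC. The ND non-EEC libraries were not alike. Replicate 1 had their lowest T cell score (3.08, against 4.02 and 4.75) and their highest enterocyte score (9.08, against 6.59 and 6.24). Leaving out replicate 1 gave 4141 genes for diet in non-EEC. The run with 1 ND non-EEC library thus does not separate sample number, lymphocytes and the choice of library. Of 99 list tests of the diet comparisons camera called 44, against 0 with an estimated correlation and 21 by fry. Fry called 2 for diet in EEC, 16 for diet in non-EEC and 3 for the difference. The reversed values were all from diet in EEC. Gcg (0.11) became -0.26 without ND EEC replicate 2, -0.16 without ND EEC replicate 3, -0.61 without HFD EEC replicate 1, -0.93 with the T cell score and -0.32 with factors computed over EEC-restricted genes. Sst became -0.50 without HFD EEC replicate 1, and with the T cell score Sst became -2.14, Ghrl -0.67, Nts -0.66, Gip -0.61, Cck -0.51, Chga -0.032 and Neurog3 0.035. Without 1 library Gcg ran up to 1.12 and Sst up to 1.98. The cause was not tested where none is given. With a replicate block the counts were 3689, 2145, 2804, 0, 2657 and 84, in the order both diets, ND, HFD, diet in EEC, diet in non-EEC and difference. The block called 64 genes with a positive and 20 with a negative difference of diet effects, against 77 and 8 without it, and 1042 genes lower in EEC under HFD, against 645. Residuals of EEC and non-EEC libraries with the same number correlated at 0.142, 0.227 and -0.013 under ND and at 0.247, 0.239 and 0.234 under HFD. Within its diet every HFD library correlated best with its own number, and so did replicates 1 and 2 of ND, while replicate 3 of ND did not. This is a hint from the data, and the labels do not say that a number marks a mouse. Chance can be excluded for EEC against non-EEC over both diets, where 1 of 100 splits, the real one, gave 3685 genes and the highest other 135. For ND (2189), HFD (2393) and diet in non-EEC (2549) 1 of 10 splits gave as many and the highest other gave 0, and for diet in EEC 10 of 10 gave 0. Those 10 splits are too few for a share below 0.05. With the depth, trended dispersions and 3 libraries per group of these data the self-test recovered 6.0% of 2-fold changes, and which of these set the limit was not tested.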

Other observations

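The hypotheses in this part and their tests were chosen after the results were seen. Lymphocyte transcripts marked the diet groups library by library. Gzma, the granzyme of cytotoxic lymphocytes, had 5811, 8000 and 16885 CPM in the ND non-EEC libraries and 263.4, 34.5 and 442 in the HFD non-EEC libraries. In EEC it had 2399, 1374 and 325 CPM under ND and 22.8, 39.9 and 92.9 under HFD. Among lists lower in EEC under HFD and not described above were carbohydrate genes (median -2.30), lipid absorption genes (-2.12), bile acid and retinoid genes (-2), xenobiotic genes (-1.97), amino acid genes (-1.90), Paneth genes (-1.73) and oxidative phosphorylation genes (-0.99). Their camera adjusted p were between 4.28e-10 and 0.00307, and 0.364 to 0.554 with an estimated correlation. Lists not called for diet in EEC, with or without any 1 library, included stem cell (median 0.10), oxidative phosphorylation (0.14) and clock genes (0.25).

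Among 791 genes restricted to EEC (called higher in EEC under both diets with a fold above 4), edgeR called 0 for diet in EEC, with 69 at an unadjusted p below 0.05. Apoa5 (3.84) and Hspb1 (3.02) had the smallest adjusted p, 0.108, with factors computed over these genes. The restriction used the same libraries and left out genes not called under either one of the diets. Pyy and Cck, not called under ND, were thus not covered by this test.

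Hormone transcripts pointed up and Neurog3 down in HFD EEC, and edgeR called none of these genes in the full data (Pyy passed by DESeq2, adjusted p = 0.0421). The hormone list was not called with an estimated correlation (adjusted p = 0.613), a variant that called 0 lists in any comparison. It pointed down with the T cell score (0.743), which itself follows diet, so neither value decides. A shift of EEC towards later differentiation was scored. The hormone minus early gene score was 0.56, -0.34 and 0.72 under ND and 2.01, 1.98 and 1.88 under HFD, a difference of 1.64 log2 units. The two-sided exact permutation test gave p = 0.1, the smallest it can give with 3 libraries against 3, and 0.2 after adjustment for 2 hypotheses. A more distal origin of the HFD EEC might also raise Pyy and Nts. The distal minus proximal score was -3.24, -4.94 and -5.32 under ND and -3.86, -2.80 and -3.83 under HFD, a difference of 1.01 (exact permutation p = 0.3, adjusted 0.3). Neither test could pass the threshold in this design. The first score holds the genes that prompted it and decides nothing, and its early genes moved both ways (Sox4 0.96, Pax4 0.12, Insm1 -0.91 and Neurog3 -1.21).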
